A study of Mus musculus with 7 samples.

How the data were processed

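Messenger RNA was profiled in retinas of ICR mice, an outbred laboratory stock, taken at embryonic day 17.5 and kept as explants for 2 days. Per the labels' protocols, the explants were electroporated with a plasmid expressing a short hairpin RNA against Kmt2f, an alias of Setd1a, or with a control plasmid, in both cases together with a plasmid for EGFP. The explants were then dissociated, EGFP-positive cells were isolated by cell sorting, cDNA was made from 1 ng of total RNA with SMART-Seq v4, and libraries were prepared by tagmentation with a Nextera DNA Flex kit. The series' design text speaks of day 17 where the sample labels give 17.5. There were 3 control libraries and 4 shKmt2f libraries. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

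Per the submitters' processing notes, the tools were Salmon 0.11.3 and sleuth 0.30.0 and the genome build was GRCm38.p6. The authors deposited 1 table per library with 1 row per transcript, in TPM, a length-scaled share of the transcripts of a library. Beside the TPM, each deposited table repeats the same p-value and q-value columns and an effect column on a natural log scale, per the file headers and the values, and these columns were identical in all 7 tables. They are used here only where the authors' deposited table is named. Each table has 55475 rows, of which 71 hold no TPM, and 55404 transcripts were used. TPM totals lay between 991445 and 992309 per library. TPM keeps no sequencing depth and no read counts were used here, so the depth behind each value is unknown and no counting interval is given. Low values are therefore less certain to an extent that the tables do not show.

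TPM was summed over the transcripts of a gene, giving 16143 genes, of which 16129 matched a symbol in the gene name table. Genes with at least 1 TPM in at least 3 libraries were tested, which left 12456 genes. The planned tests were for read counts, but the deposited unit is TPM, which is not a count, so the tests were replaced by those the unit allows. The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-dependent prior for the spread, robust estimation, the group as the only term and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. A fold change is on the log2(TPM + 1) scale throughout, shKmt2f minus control, and understates the change of genes of low level. No further scaling was applied. For single values an exact permutation test, two-sided, was run over all 35 splits of the 7 libraries into 3 and 4, whose smallest possible p is 0.0286. For levels it used log2(TPM + 0.1) for single transcripts and log2(TPM + 1) for sums over a gene. The same limma model was fitted to single transcripts.

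Before the data were examined, 39 gene lists were fixed: chromatin complexes, cell cycle, DNA repair, stress and metabolic programs, signalling pathways, neuronal genes, and markers of the retinal and non-retinal cell types that the sorted cells could include. The 36 lists with at least 3 measured members were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and two-sided. The estimated correlation and fry were alternatives. The rule for named genes was also fixed then. It takes Setd1a, Setd1b, Uhrf1 and any other methyltransferase complex member past the threshold; the 10 protein-coding genes with the largest positive and the 10 with the largest negative fold change among those past the threshold, with a mean of at least 5 TPM and group ranges that do not overlap; and up to 4 passing members of each list with the smallest adjusted p, or up to 2 members given as values where none passed. A few list members that this rule takes are not reported here. The rule was written for CPM and was applied to TPM.

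Positions are from the GRCm38 annotation. Transcript sequence gave GC content and length for 12453 of the 12456 tested genes. Of 1516 annotated pseudogenes in the tables, 1164 matched a protein-coding transcript at 90% identity over at least 50% of their length with blastn 2.17.0. Genes whose pseudogene copies carry much of the summed TPM are named as uncertain beside their values, since reads may have been shared between the copies.

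Alternatives were median-ratio scaling, no filter, a pseudocount of 0.1, a per-library loess correction on GC content (span 0.3), the replicate number as a block, leaving out each library, and further thresholds and filters. Chosen after seeing the data were a correction on GC content and then transcript length, adding pseudogenes to their parent genes, summing protein-coding transcripts only, weighting TPM by transcript length before summing, leaving out X and Y, a pseudocount of 0.1 for transcripts, and 1 surrogate variable as a covariate in limma. It was estimated on log2(TPM + 1), either in 2 steps from the residuals or by iterated weighting of the genes. The estimated correlation was also run after the correction on GC content and length. The model was tested on data simulated 20 times with the means and spread of the 12456 genes and 200 genes changed by known amounts. For this comparison it recovered 15.3% of genes changed by 0.5 on the log2 scale, 65.7% at 1, 86.9% at 1.5 and 94.2% at 2. Of its 2746 calls in the simulations, 125, or 4.55%, were false, with a range of 0.781% to 8.90% over the 20 draws. The noise was drawn independently for each gene. The simulated libraries thus hold no shared trend, such as one on GC content, and no correlation between genes. The changed genes were taken only from those with a mean log2(TPM + 1) above the level of 5 TPM. These rates may therefore not carry over to the real libraries. Summaries and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.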

Results

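Transcript levels were compared between EGFP-sorted cells of embryonic mouse retina explants that had received a control plasmid (n = 3 libraries) and cells that had received a knockdown plasmid against Setd1a (n = 4 libraries), to ask which transcripts change when this histone H3 lysine 4 methyltransferase is reduced. Each library held between 11840 and 12318 genes with at least 1 TPM. Depth is unknown because TPM does not keep it. Pseudogenes took between 24.2% and 30.9% of the TPM of a library. Control replicate 2 correlated more closely with shKmt2f replicate 3 (Pearson r = 0.978 across genes, which are not independent replicates) than with control replicate 1 (r = 0.973).

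The targeted gene was examined first. Setd1a (ENSMUSG00000042308) lies on chromosome 7 from 127776670 to 127800122 on the plus strand of GRCm38. Its longest listed transcript, of 6487 bases, stood at 0.830 ± 0.112 TPM in the control libraries (SD, n = 3) and at 0.385 ± 0.0451 TPM in the shKmt2f libraries (SD, n = 4), or 46.4% of control, with an exact permutation p of 0.0286, the smallest the design allows. The control libraries had 0.767, 0.959 and 0.764 TPM of it and the shKmt2f libraries 0.407, 0.328, 0.374 and 0.432 TPM. All these values lie below the level needed for the limma test. In the authors' deposited table the effect for this transcript is -0.85 on the natural log scale, with q = 1.74e-05. The sum over all Setd1a transcripts is dominated by short ones, among them a transcript of 315 bases at 4.92 ± 1.46 TPM in control and 3.65 ± 1.41 TPM in shKmt2f libraries. That sum was 8.95 ± 2.36 against 6.94 ± 1.71 TPM, and its log2 fold change of -0.33 (SE 0.23) did not pass in limma, adjusted p = 0.365. For Setd1a the exact permutation test had been planned on the gene, and on the sum it gave p = 0.4. The other listed transcripts, of 315, 389 and 730 bases, had exact permutation p of 0.257, 0.914 and 0.886. Weighted by transcript length before summing, a choice made after seeing the data, the log2 fold change was -0.78 (SE 0.17), limma adjusted p = 0.0223.

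**Figure D1:**
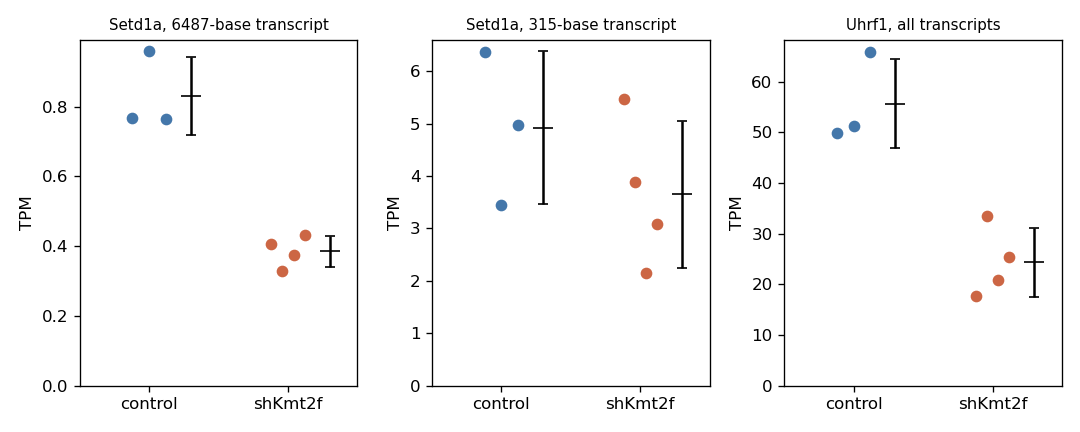
TPM (vertical axes, from 0) of the longest listed Setd1a transcript, of a short Setd1a transcript and of the sum of Uhrf1 transcripts in each control and shKmt2f library (points), with the mean and SD of each group (bars). The longest Setd1a transcript lies between 0.764 and 0.959 TPM in control libraries and between 0.328 and 0.432 TPM in shKmt2f libraries, while the groups overlap for the 315-base transcript.

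Uhrf1 (ENSMUSG00000001228; chromosome 17, 56303321 to 56323486), which links DNA methylation maintenance to replication, fell from 55.7 ± 8.83 to 24.4 ± 6.84 TPM, a log2 fold change of -1.19 (SE 0.21) with limma adjusted p = 0.0170. Without control replicate 3 its adjusted p was 0.0588. Setd1b, the paralog of Setd1a, stood at 0.436 ± 0.101 and 0.403 ± 0.135 TPM, below the level needed for the test (exact permutation p = 0.771). Its transcript of 8857 bases alone stood at 0.279 ± 0.0193 TPM in control and 0.197 ± 0.0275 TPM in shKmt2f libraries, or 70.6% of control, with an exact permutation p of 0.0286. In the authors' deposited table this transcript has an effect of -0.44 and q = 0.201. Weighted by transcript length, the Setd1b sum had an exact permutation p of 0.0571 and a limma adjusted p of 0.206. Of the 18 measured members of the lysine 4 methyltransferase complexes, 1 passed, or 3 without control replicate 2. It was Kdm6a, an X-linked histone demethylase carried by some of these complexes (chromosome X, 18162575 to 18279936), which rose from 8.06 ± 4.28 to 27.8 ± 5.63 TPM (log2 fold change 1.79, SE 0.36, limma adjusted p = 0.0226). The Kdm6a call was lost without shKmt2f replicate 1 or 2, with adjusted p of 0.0651 and 0.0665. Its Y-linked paralog Uty stood at 1.78 and 2.24 TPM in control replicates 1 and 2 and at no more than 0.0929 TPM in the other 5 libraries.

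Across the 12456 genes tested with limma, 1755 passed at an adjusted p of 0.05, of which 1295, or 73.8%, were higher in shKmt2f libraries and 460 were lower. Median-ratio scaling moved the median of all genes by -0.11 and gave 1940 calls, of which 1119, or 57.7%, were higher. The share of higher calls is relative to that shift. Among the called genes, 733 of the 1295 higher ones lay in the lowest of 5 equal bins of GC content. From the shortest to the longest of 5 equal bins of transcript length, the higher calls numbered 107, 154, 256, 368 and 410, and the median log2 fold change went from -0.09 to 0.28. The slope of a library on transcript length lay between -0.131 and -0.0212 per doubling in control and between 0.0020 and 0.107 in shKmt2f libraries (exact permutation p = 0.0286). Correcting each library for GC content left 881 calls, 543 of them higher, and correcting for GC content and length left 801, 522 of them higher. A surrogate variable in the limma model gave 3540 calls when estimated in 2 steps and 809 when estimated by iteration. The count was 292, 3024 and 361 without control replicate 1, 2 and 3, and 282, 320, 501 and 504 without shKmt2f replicate 1, 2, 3 and 4. The higher calls were 49.7%, 80.7% and 62.3% of these without control replicate 1, 2 and 3, and 52.1%, 48.8%, 66.5% and 60.1% without shKmt2f replicate 1, 2, 3 and 4. Without control replicate 1 there were thus 145 higher and 147 lower calls, and without shKmt2f replicate 2 there were 156 and 164.

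**Figure D2:**
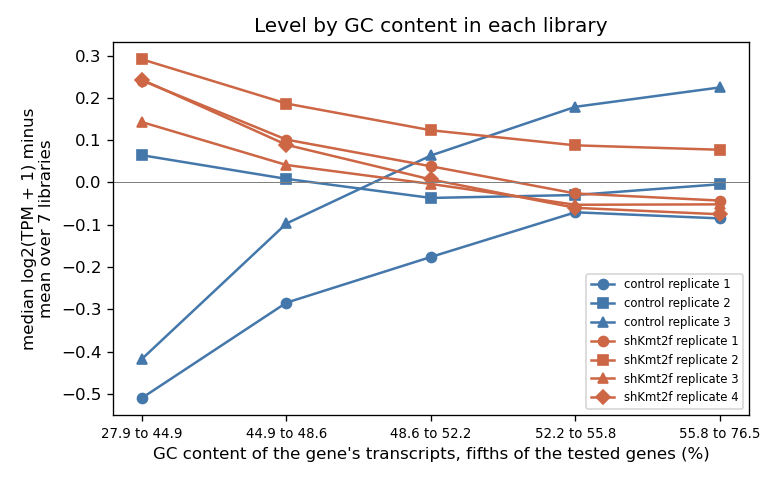
Median log2(TPM + 1) of the genes in each of 5 bins of GC content, minus each gene's mean over the 7 libraries (vertical axis), for each library (lines), against the GC range of the bin in percent (horizontal axis). In the lowest bin, control replicates 1 and 3 lie at -0.51 and -0.42, control replicate 2 at 0.06 and the shKmt2f libraries between 0.14 and 0.29.

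Among the genes with the largest falls, Rsph1, a radial spoke component of motile cilia (chromosome 17, 31255019 to 31277383), went from 24.2 ± 5.70 to 3.07 ± 0.654 TPM, a log2 fold change of -2.61 (SE 0.20, limma adjusted p = 0.00101). Rdm1, which takes part in DNA recombination, fell from 45.0 ± 6.63 to 10.8 ± 1.10 TPM (log2 fold change -1.96, limma adjusted p = 0.000943). Fkbp1a, an immunophilin that binds FK506 (chromosome 2, 151542483 to 151561692), fell from 323.3 ± 43.4 to 97.9 ± 4.92 TPM (log2 fold change -1.71, SE 0.11, limma adjusted p = 0.000569). Ormdl2, a regulator of sphingolipid synthesis, fell from 63.1 ± 2.84 to 20.97 ± 2.13 TPM, and the alpha tubulin gene Tuba1c from 42.6 ± 3.07 to 14.8 ± 2.18 TPM. The neuropeptide gene Npy fell from 15.6 ± 3.99 to 4.43 ± 0.892 TPM and Fam183b from 16.9 ± 5.42 to 3.58 ± 1.74 TPM. Ndufa4l2, known as a hypoxia-induced mitochondrial protein, fell from 122.5 ± 46.3 to 32.0 ± 9.09 TPM. Each of these 8 genes kept its call without any 1 library and after correction for GC content and length. The lactate transporter gene Slc16a3 and the cationic amino acid transporter gene Slc7a3 complete the 10, with log2 fold changes of -2.21 and -1.87. Both lost their calls without shKmt2f replicate 2 or 3, Slc16a3 also after the GC correction (adjusted p = 0.0939).

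Among the 10 genes with the largest rises, Carmil1, a regulator of actin capping (chromosome 13, 24012344 to 24280795), rose from 4.83 ± 2.67 to 24.3 ± 6.03 TPM, a log2 fold change of 2.22 (SE 0.35, limma adjusted p = 0.0129). Fggy, which encodes a carbohydrate kinase (chromosome 4, 95557507 to 95926939), rose from 7.74 ± 2.97 to 30.1 ± 6.15 TPM (log2 fold change 1.88, SE 0.26, limma adjusted p = 0.0107). These 2 genes kept their calls without any 1 library and after the GC and length correction. Top2b, the topoisomerase of postmitotic neurons, rose from 36.0 ± 34.6 to 120.6 ± 21.3 TPM, and Angpt1, a ligand of the Tie2 receptor, from 3.46 ± 2.73 to 13.8 ± 2.09 TPM. Zfp758, Zfp280d, Manea, Gm17655, Gm21586 and the iron exporter gene Slc40a1 are the others, with log2 fold changes between 1.88 and 3.22. The 3.22 is that of Gm21586, which was listed at 0 TPM in control replicates 1 and 2 and at 7.22 TPM in control replicate 3. These 8 genes lost their calls without shKmt2f replicate 1 and without control replicate 1, and Top2b also after the GC correction (adjusted p = 0.0529), as did Slc40a1 (adjusted p = 0.0685).

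Many genes of the cell cycle were lower in the shKmt2f libraries. Of 42 measured genes of mitosis, 19 fell and 0 rose, or 22 and 1 adjusted over the list alone, with a median log2 fold change of -0.52. The falls numbered 10, 18 and 9 without control replicate 1, 2 and 3, and 11, 12, 10 and 12 without shKmt2f replicate 1, 2, 3 and 4. Without control replicate 2 there were also 8 rises. Cdc20, an activator of the anaphase-promoting complex, fell from 291.2 ± 36.1 to 109.8 ± 15.6 TPM, the mitotic cyclin gene Ccnb1 from 176.3 ± 11.5 to 67.2 ± 13.8 TPM, the centromeric histone gene Cenpa from 165.6 ± 18.2 to 75.2 ± 9.62 TPM and Ube2c from 136.2 ± 14.0 to 60.3 ± 8.26 TPM. Of 45 measured genes of DNA replication, 10 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.27. Without control replicate 1, 2 and 3 the replication falls numbered 3, 8 and 1, and without shKmt2f replicate 1, 2, 3 and 4 they numbered 1, 3, 1 and 3. Without control replicate 2 there was also 1 rise. The 10 genes include Gins2 and Chaf1b, with log2 fold changes of -0.74 and -0.63, Pold1 at -0.67, and Rrm2 at -1.02, whose pseudogene copies hold 233.0 TPM, so that its level is uncertain. The camera adjusted p was 8.95e-09 for mitosis and 5.64e-09 for replication. With an estimated correlation both had adjusted p = 0.525. Replication-dependent histone genes had 4 lower and 1 higher of 9 (5 and 1 adjusted over the list alone), with Hist1h2bk, Hist1h1c and Hist1h2ae lower and Hist1h4d higher. Levels were low, with Hist1h2bk at 4.34 ± 0.191 and 1.09 ± 0.588 TPM in control and shKmt2f libraries. Hist1h4d stood at 0.198 ± 0.108 and 2.01 ± 0.167 TPM. Hist1h1c, the highest of these 4, had a log2 fold change of -0.96. How fully the cDNA method recovers histone RNA was not tested, so these values may not stand for all of it. The histone falls numbered 0, 5 and 1 without control replicate 1, 2 and 3, and 2 without any 1 shKmt2f library. Camera gave adjusted p = 0.00934, and adjusted p = 0.525 with an estimated correlation. With the GC and length correction the falls numbered 12 for mitosis, 7 for replication and 2 for the histones. Gins2, Chaf1b, Pold1 and Hist1h2ae then lost their calls, with adjusted p between 0.0625 and 0.0868.

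**Figure D3:**
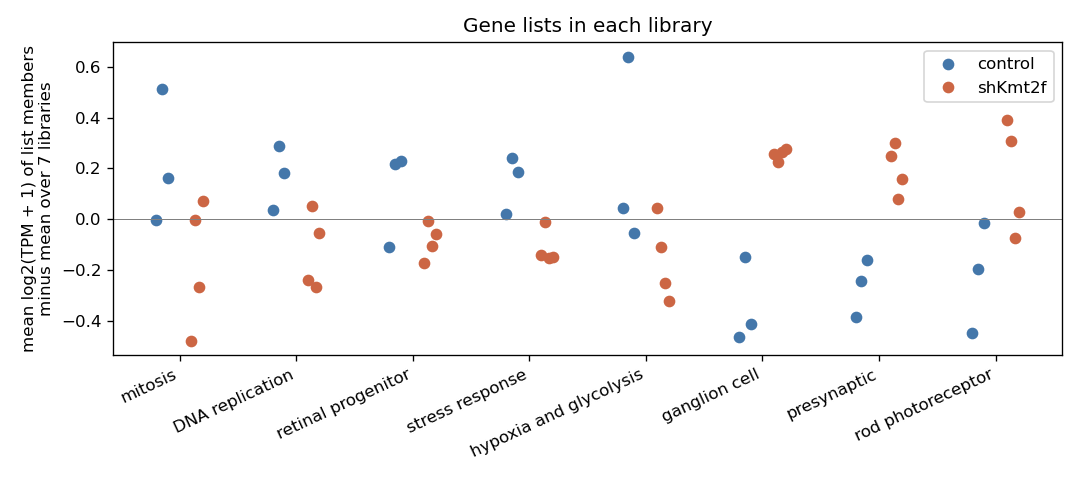
Mean log2(TPM + 1) of the members of 8 gene lists minus the mean over the 7 libraries (vertical axis), with 1 point for each control and shKmt2f library. For ganglion cell markers the control libraries lie between -0.46 and -0.15 and the shKmt2f libraries between 0.23 and 0.28, while for mitosis the lowest control library, at -0.0017, lies below the highest shKmt2f library, at 0.07.

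Markers of retinal progenitors showed 4 lower and 0 higher of 24 measured genes (5 and 0 adjusted over the list alone), with a median log2 fold change of -0.18. Without shKmt2f replicate 1 the count was 2 lower and 0 higher, and without control replicate 2 it was 5 and 1. The mean of the list, on log2 against all libraries, was -0.108, 0.217 and 0.231 in control replicates 1, 2 and 3. It lay between -0.172 and -0.0075 in shKmt2f libraries, so control replicate 1 fell within their range. The cyclin gene Ccnd1, expressed in dividing retinal progenitors, fell from 130.0 ± 13.5 to 65.2 ± 5.41 TPM, the Notch effector Hes5 from 363.8 ± 28.0 to 222.3 ± 13.5 TPM, Dapl1 from 207.5 ± 37.4 to 115.5 ± 15.4 TPM, and Id1 from 28.3 ± 2.75 to 19.7 ± 2.03 TPM. The camera test gave adjusted p = 0.0045 for this list and adjusted p = 0.601 with an estimated correlation. In the Notch pathway list, 2 of 16 genes fell, Hes5 and Lfng, and 0 rose, with the same counts adjusted over the list alone. In camera the list had adjusted p = 0.0105, and adjusted p = 0.639 with an estimated correlation. The Notch falls numbered 1 without any 1 library other than control replicate 2, without which 2 fell and 1 rose. The list's call was lost without control replicate 3 (adjusted p = 0.0761) and after the GC correction (adjusted p = 0.107), but not after the GC and length correction (adjusted p = 0.0251). Markers of neurogenic progenitors went both ways, with 5 higher and 2 lower of 21 (6 and 4 adjusted over the list alone). Neurod4 rose from 230.8 ± 95.2 to 684.9 ± 94.5 TPM and Neurod1 from 164.5 ± 64.5 to 434.1 ± 65.5 TPM, both transcription factors of neuronal differentiation. The antiproliferative gene Btg2 rose from 90.8 ± 14.2 to 163.3 ± 17.0 TPM, while Hes6 fell from 1227 ± 143.0 to 861.4 ± 48.8 TPM. The rises numbered 3, 7 and 3 without control replicate 1, 2 and 3, and 3, 3, 4 and 4 without shKmt2f replicate 1, 2, 3 and 4, and the falls 1, 3, 0, 0, 0, 0 and 1 in that order. The list as a whole did not pass (camera adjusted p = 0.387). Hes5, Lfng, Id1 and Hes6 lost their calls after the GC and length correction, with adjusted p between 0.0613 and 0.329. The falls then numbered 2 among progenitor, 0 among Notch and 0 among neurogenic genes, of which 3 rose.

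Several markers of retinal neurons were higher. Of 12 measured markers of ganglion cells, the output neurons of the retina, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.74. The rises numbered 0, 8 and 1 without control replicate 1, 2 and 3, and 2, 2, 3 and 2 without shKmt2f replicate 1, 2, 3 and 4. Gap43, a growth cone protein, rose from 10.6 ± 2.46 to 22.1 ± 2.51 TPM, Isl2 from 3.18 ± 0.516 to 7.66 ± 1.84 TPM and Ebf1 from 3.43 ± 0.721 to 7.62 ± 1.71 TPM. Camera gave adjusted p = 0.00366 and, with an estimated correlation, adjusted p = 0.525. Of 17 presynaptic and other neuronal genes 6 rose and 0 fell (9 and 0 adjusted over the list alone), among them Snap25, from 48.6 ± 17.8 to 100.8 ± 9.09 TPM, Syp, from 105.2 ± 10.6 to 152.2 ± 18.3 TPM, and Map2, a dendritic microtubule protein. The rises of these genes numbered 1, 7 and 1 without control replicate 1, 2 and 3, and 1, 1, 2 and 3 without shKmt2f replicate 1, 2, 3 and 4. The camera test gave adjusted p = 0.00934 for them, and adjusted p = 0.525 with an estimated correlation. In a list of chromatin and neuronal genes chosen for their place in work on SETD1A deficiency, 4 of 7 rose and 0 fell (5 and 0 adjusted over the list alone). The axon guidance receptor gene Robo2 rose from 21.7 ± 6.07 to 68.7 ± 11.6 TPM, and Mef2a and Ank3 rose as well. The rises of this list numbered 1, 4 and 1 without control replicate 1, 2 and 3, and 1, 1, 2 and 2 without shKmt2f replicate 1, 2, 3 and 4. In camera the list had adjusted p = 0.00775, and adjusted p = 0.525 with an estimated correlation. Markers of horizontal cells had 2 of 5 higher and 0 lower (3 and 0 adjusted over the list alone), Onecut1 and Ndnf. Both were of low level, with Onecut1 at 0.586 ± 0.244 and 1.70 ± 0.411 TPM and Ndnf at 2.88 ± 1.61 and 6.79 ± 1.26 TPM. Onecut1 reached 1 TPM only in shKmt2f libraries and is also counted among the rises of the neurogenic list. Camera gave adjusted p = 0.0447, and adjusted p = 0.525 with an estimated correlation. This call was lost without control replicate 2 or 3, without shKmt2f replicate 1 or 2, and after the GC correction (adjusted p = 0.115). Of the horizontal cell markers 3 rose without control replicate 2, 1 without shKmt2f replicate 3, and 0 without any 1 of the other 5 libraries. Mef2a, Ank3, Onecut1 and Ndnf lost their calls after the GC and length correction, with adjusted p between 0.0529 and 0.0832, which left 2 rises in the list of chromatin and neuronal genes and 0 among horizontal cell markers.

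Photoreceptor genes were mixed. Of 26 rod markers, 2 rose and 1 fell, with the same counts adjusted over the list alone. The rod-promoting regulator Prdm1 rose from 37.3 ± 10.4 to 91.2 ± 14.6 TPM and Crx, the transcription factor of both photoreceptor types, from 62.3 ± 9.35 to 102.8 ± 20.2 TPM. Gnb1, a transducin subunit, fell from 536.1 ± 7.66 to 350.2 ± 53.8 TPM. The camera test gave adjusted p = 0.0383 for the rod list and adjusted p = 0.720 with an estimated correlation. The call was lost without control replicate 2 (adjusted p = 0.245) and without shKmt2f replicate 1 (adjusted p = 0.101). Of 7 cone markers 2 rose and 0 fell (3 and 0 adjusted over the list alone), Cngb3 and Gnat2, the latter with pseudogene copies at 20.4 TPM. Of 8 bipolar cell markers 4 rose and 0 fell, with the same counts adjusted over the list alone, namely Pcp2, from 13.6 ± 2.48 to 29.7 ± 4.32 TPM, Gng13, Isl1 and Lhx4. The cone and bipolar lists did not pass in camera, with adjusted p = 0.132 and 0.0513, but did after the GC and length correction, with adjusted p = 0.0427 and 0.0232. With an estimated correlation both had adjusted p = 0.525 before and adjusted p = 0.486 after that correction. Amacrine cell markers had 3 higher and 1 lower of 17, with the same counts adjusted over the list alone, where Meis2, Isl1 and Tfap2b rose and C1ql1 fell (camera adjusted p = 0.700). Müller glia markers had 2 higher and 5 lower of 20 (4 and 5 adjusted over the list alone), where Glul, Espn and Crym fell and Cp rose (camera adjusted p = 0.734). The Müller glia falls numbered 2, 5 and 0 without control replicate 1, 2 and 3, and 1, 1, 1 and 3 without shKmt2f replicate 1, 2, 3 and 4, and the rises 0 except for 2 without control replicate 2. In the same order of left-out libraries, the rises numbered 1, 3, 1, 1, 1, 1 and 2 for rod, 1, 2, 2, 1, 1, 1 and 2 for cone, 1, 3, 3, 1, 1, 2 and 2 for bipolar and 1, 5, 1, 0, 0, 1 and 1 for amacrine markers. The rod fall was left without control replicate 2 or shKmt2f replicate 1, and the amacrine fall was lost without shKmt2f replicate 1. Glul, Espn, Crym and Cp lost their calls after the GC and length correction, with adjusted p of 0.116, 0.0974, 0.0756 and 0.0675, and the Müller glia falls went from 5 to 1. Crx, Cngb3 and C1ql1 lost theirs too, with adjusted p of 0.0591, 0.0587 and 0.0624.

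With all 7 libraries in the fit, more genes of the integrated stress response and of hypoxia and glycolysis fell than rose. Of 22 genes of the integrated stress and unfolded protein responses, 7 fell and 1 rose (9 and 1 adjusted over the list alone). The stress falls numbered 5, 8 and 4 without control replicate 1, 2 and 3, and 4, 7, 4 and 4 without shKmt2f replicate 1, 2, 3 and 4. The rises numbered 3 without control replicate 2 and 0 without any 1 other library. Phgdh, an enzyme of serine synthesis, fell from 41.7 ± 2.76 to 15.5 ± 2.71 TPM, the asparagine synthetase gene Asns from 37.7 ± 3.41 to 19.5 ± 2.78 TPM, Nupr1 from 52.4 ± 10.4 to 25.4 ± 2.46 TPM and Sdf2l1 from 24.0 ± 0.186 to 12.8 ± 1.01 TPM. In camera the list had adjusted p = 0.000275 and, with an estimated correlation, adjusted p = 0.525. Of 24 genes of hypoxia and glycolysis, 5 fell and 0 rose (9 and 2 adjusted over the list alone). The glycolysis falls numbered 2, 3 and 2 without control replicate 1, 2 and 3, and 3, 1, 2 and 2 without shKmt2f replicate 1, 2, 3 and 4. Without control replicate 2 there were also 3 rises, as many as falls. The mean of this list, on log2 against all libraries, was 0.640 in control replicate 2. It was 0.046 and -0.052 in control replicates 1 and 3 and lay between -0.321 and 0.046 in shKmt2f libraries. The level of the list thus rested largely on control replicate 2, and the groups otherwise overlapped. Eno1 fell from 2150 ± 321.8 to 1303 ± 150.0 TPM and the glucose transporter gene Slc2a1 from 381.6 ± 62.0 to 250.0 ± 36.6 TPM. Gapdh and Pgam1 fell with uncertain levels because of pseudogene copies at 810.9 and 31.2 TPM. All 4 of these genes lost their calls after the GC and length correction, with adjusted p of 0.220, 0.143, 0.257 and 0.0863, and the glycolysis falls went from 5 to 2. The log2 fold change of Eno1 went from -0.72 to -0.39. Camera gave adjusted p = 5.13e-05, and adjusted p = 0.578 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 1 lower of 40, Atp5c1, and 0 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 8.39e-06, and adjusted p = 0.525 with an estimated correlation). Ribosomal protein genes had 0 of 56 past the threshold in limma (8 at an unadjusted p under 0.05), and 0 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 5.13e-05, and adjusted p = 0.720 with an estimated correlation). The mean of the ribosomal list, on log2 against all libraries, was 0.298 in control replicate 1 and -0.369 in shKmt2f replicate 2. The other libraries overlapped, with -0.063 and 0.025 in control and between -0.0071 and 0.089 in shKmt2f. Of the 13 messenger RNAs of the mitochondrial genome 2 rose and 0 fell, mt-Atp8 and mt-Cytb (8 and 0 adjusted over the list alone). Without control replicate 2, 10 of these 13 rose, 4 oxidative phosphorylation genes fell and 1 rose, and 1 ribosomal protein gene rose and 1 fell. Without any 1 other library all these counts were 0. The camera test gave adjusted p = 0.00775, and adjusted p = 0.646 with an estimated correlation. After the GC and length correction the medians of these last 3 lists were 0.0038, 0.08 and 0.10, and none of the 3 passed in camera, with adjusted p of 0.112, 0.708 and 0.795. Of single genes, mt-Atp8 and mt-Cytb then lost their calls (adjusted p = 0.0524 and 0.623), and 1 ribosomal protein gene rose and 1 fell.

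At the level of single transcripts, limma called 828 of 37024 transcripts, 534 higher and 294 lower. The authors' deposited table holds 3058 transcripts with q under 0.05, 1902 of them higher and 1156 lower. Of 2800 such transcripts among those tested here, 626 were also called here, where independent lists would share 62.6, and all 626 had the same direction in both. Both lists rest on the same libraries. The count of called transcripts was 64, 4384 and 164 without control replicate 1, 2 and 3, and between 65 and 101 without any 1 shKmt2f library (65, 99, 87 and 101 without replicate 1, 2, 3 and 4).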

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

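The test of embryo sex on the mitosis genes was set before its value was seen. Its reading was changed afterwards, from one that favoured sex to one that decides nothing. The other tests in this part except the counts of splits were chosen only after the results were seen. Among 148 genes and lists examined for a shKmt2f library far from the other 3, 6 stood out, where chance gives about 7.4, so these may be chance flags. The gap to the nearest library, divided by the range of the group, was 0.890 for Pold1 (replicate 2 higher, 32.6 TPM), 0.943 for Gnb1 (replicate 1 lower, 269.6 TPM), 0.861 for Dct (replicate 1 lower, 5.34 TPM) and 0.904 for Smo (replicate 2 higher, 34.8 TPM). It was 0.918 for the integrated stress list and 0.920 for the p53 target list, in both cases with shKmt2f replicate 2 higher.

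The real grouping called 1755 genes and 828 transcripts, and 1 of the 35 splits of the libraries into 3 and 4, the real one, gave as many of either. The highest counts among the other splits were 14 genes and 11 transcripts (exact permutation p = 0.0286 for each count, the smallest possible). That is the limit of what 35 splits can show. A culture or batch that follows the groups is not addressed by it, since the labels do not say that libraries of a group were separate. For the gene lists called by camera with a preset correlation, 3 of the 35 splits gave at least the 15 lists of the real one. The highest other split gave 16 lists, so chance cannot be excluded for that count.

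The first pattern is that 1295 genes were called higher in shKmt2f libraries, 733 of them in the lowest bin of GC content. After the GC correction 36.7% of these genes were still called higher. That argues against a GC-dependent bias of the libraries as the whole cause only as far as the correction removes such a bias in full. The correction says nothing about what caused the GC trend it removes. As the cause of that trend, and so of part of the calls, a bias may hold, since the GC slope varied among the 3 control libraries by 1.27 times the difference between the group means. The slope also followed the groups: per 10 points of GC it lay between -0.04 and 0.41 in control and between -0.18 and -0.12 in shKmt2f libraries (exact permutation p = 0.0286, the smallest possible). A biological difference that follows GC content is therefore not separated from such a bias by any test here.

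The next pattern is in Y-linked RNA. Uty stood at 1.78 and 2.24 TPM and Eif2s3y at 1.85 and 3.52 TPM in control replicates 1 and 2, against 0.0929 and 0.154 TPM in control replicate 3 and at most 0.0425 and 0.0601 TPM in the shKmt2f libraries, so the sex of the embryos may differ between libraries and in part between groups. Kdm5d, which is also Y-linked, stood at 2.32, 3.37 and 1.26 TPM in control and between 1.17 and 1.42 TPM in shKmt2f libraries. It was thus also highest in control replicates 1 and 2, but was listed above 1 TPM in every library. Whether reads of other genes were counted in Kdm5d was not tested, so it does not settle the sex of the embryos. As a cause of the called genes, whole or in part, the sex of the embryos stays open, because it may partly follow the groups and the labels give no sex. X-linked genes made up 4.50% of the called and 3.48% of the tested genes, a ratio of 1.29 with an exact 95% binomial interval from 1.03 to 1.60. The interval lies above 1, so X-linked genes were more frequent among the called than among the tested genes. It treats genes as independent, which they are not. Whether X-linked genes are concentrated to 1.5 times, a bound chosen after the result, is not decided. Without X and Y the count of called genes was 1677.

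The last pattern is the lower level of mitosis and replication genes. GC bias as the whole cause is argued against by the median of the mitosis list, -0.52 both before and after the GC and length correction, though the genes past the threshold went from 19 to 12 for mitosis and from 10 to 7 for replication. For the sex of the embryos, the rule set beforehand took an overlap of the groups as what sex would give. That rule was met, with -0.0017 in the lowest control library and 0.07 in the highest shKmt2f library. It was read afterwards as deciding nothing, since the overlap came from control replicate 1. Control replicate 3, which had little Uty or Eif2s3y RNA, lay at 0.16, above all 4 shKmt2f libraries. That is 1 library, looked at after the result, and excludes nothing, so the sex of the embryos stays open here too. A lower share of progenitor cells stays open and cannot be told apart from an effect of the knockdown on cycling within progenitors, since the quartiles of the progenitor markers, -0.44 and 0.10, overlap those of the mitosis list, -0.92 and 0.12.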

How the results depend on the processing

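The GC and length correction, the length-weighted sum, the other gene-summing choices, leaving out X and Y, the surrogate variables, and the transcript pseudocount were chosen after seeing the data. The count of called genes, 1755, stayed within 1.5 times between 1333 without the filter and 2500 with the length-weighted sum, except for 881 with the GC correction, 801 with the GC and length correction, 650 with the replicate block and the GC correction, 3047 at an adjusted p of 0.10, and 3540 and 809 with 1 surrogate variable estimated in 2 steps and by iteration. It lay between 282 and 3024 with 1 library left out, where fewer libraries enter the fit. Of the 1295 higher and 460 lower calls, 475 and 241 were kept after the GC correction and 1077 and 445 after median-ratio scaling. For Setd1a the fold change was negative under all 24 alternatives, from -0.03 to -0.78. Some of these, such as leaving out the filter or X and Y, cannot change its value of -0.33. The -0.03, after the GC and length correction, is well within its SE of 0.22 (limma adjusted p = 0.939). Setd1a passed only with the length-weighted sum (-0.78, adjusted p = 0.0223), which gives the long transcript more weight. With 1 library left out it lay between -0.44 and -0.14. The count of 15 called lists became 0 with an estimated correlation, also after the GC and length correction. Before that correction the lowest adjusted p was 0.525 and 2 lists had an unadjusted p under 0.05. The count was 8 with fry and lay between 13 and 16 with 1 library left out. The 8 included the cone, bipolar and pigment epithelium lists, which camera did not call (fry adjusted p = 0.0270, 0.0313 and 0.0152). Fry did not call the mitosis and replication lists (adjusted p = 0.0958 and 0.0932). Nor did it call the progenitor, glycolysis, Notch and ribosomal lists (adjusted p = 0.176, 0.179, 0.251 and 0.489). The histone, rod, oxidative phosphorylation and mitochondrial lists each had fry adjusted p = 0.121. Of the 15, 11 kept their call and direction after the GC and length correction. The count of 828 transcripts became 302 without the filter and 365 with a pseudocount of 0.1, and lay between 64 and 4384 with 1 library left out. Except where stated, the cause was not tested.

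Of the 102 named genes that passed, 43 to 62 kept their call with 1 library left out other than control replicate 2, and 99 without that one. After the GC correction 70 of the 102 kept it, after the GC and length correction 62, with the replicate block 81, and with the block and the GC correction 56. It was kept by 97 and 77 with the surrogate variable in 2 steps and by iteration. The median of the mitochondrial messenger RNA list lost its call and camera's direction turned with the GC correction (0.012) and with the replicate block and the GC correction (-0.00698), and Rpsa, which did not pass, turned to 0.11 with the GC and length correction. Replicate numbers did not clearly pair the libraries across the groups. Same-numbered libraries deviated together with correlations of 0.08, 0.07 and 0.06, and differently numbered ones with correlations between -0.169 and 0.098. Not every library correlated best with its own number. With so few libraries this does not exclude that equal numbers share a culture or batch. Within the shKmt2f group, replicates 1 and 2 (Pearson r = 0.986) and replicates 3 and 4 (r = 0.988) were closer than the other pairs (0.975 to 0.978). The labels do not say whether these libraries shared a culture or batch. If they did, the p-values rest on fewer independent units than libraries. With the replicate block, which leaves out shKmt2f replicate 4, 1391 genes, 17 lists and 1 transcript were called. Not run were TMM, the length offset and the count models of the plan, edgeR and DESeq2, with the surrogate variable planned for edgeR, since they are made for counts. Depth is unknown, so it could not be said which low values it limits.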

Other observations

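The groups of genes not described so far were mostly chromatin, damage and non-neuronal markers. Of 14 polycomb genes 4 rose and 0 fell (6 and 0 adjusted over the list alone). Bmi1 went from 36.3 ± 22.6 to 100.6 ± 7.95 TPM, and Mtf2, Rnf2 and Suz12 had log2 fold changes of 0.66, 0.95 and 1.20 (limma; camera adjusted p = 0.184). After the GC and length correction, chosen after seeing the data, 1 of these 4 calls was left, Bmi1 (limma adjusted p = 0.0281). The polycomb rises numbered 5 without control replicate 2, 1 without shKmt2f replicate 4 and 0 without any 1 of the other 5 libraries. Of 8 lysine 4 demethylases 1 rose, Kdm5a, with a log2 fold change of 0.73, and the same count held adjusted over the list alone (camera adjusted p = 0.215). Of 11 DNA methylation genes 1 fell, Uhrf1, again with the same count adjusted over the list alone (camera adjusted p = 0.734). The lysine 4 methyltransferase list itself had a camera adjusted p of 0.734. Of 27 p53 targets 5 rose and 2 fell (6 and 2 adjusted over the list alone), among the former Trp53inp1, from 7.97 ± 2.63 to 25.4 ± 3.91 TPM, Mdm2, from 45.1 ± 7.36 to 76.3 ± 6.56 TPM, and Plk2, from 5.41 ± 0.279 to 11.0 ± 1.95 TPM (camera adjusted p = 0.475). The p53 target rises numbered 2, 7 and 2 without control replicate 1, 2 and 3, and 2, 3, 4 and 4 without shKmt2f replicate 1, 2, 3 and 4, and the falls 0 except for 1 without control replicate 2. Cell cycle inhibitors had 2 higher, Btg2 and Rb1, and 1 lower, Cdkn2c, of 10 (camera adjusted p = 0.734). The list of apoptosis genes did not pass (camera adjusted p = 0.734). Genes of homologous recombination and the Fanconi pathway had 1 higher, Fancm, of 33 (camera adjusted p = 0.323). The counts for the inhibitors and for the recombination genes were the same adjusted over the list alone. Without control replicate 2, 6 recombination genes, 2 demethylases and 3 DNA methylation genes rose. The demethylase rise was lost without any 1 other library, and the Uhrf1 call without control replicate 3. The inhibitor rises numbered 1 without any 1 library other than control replicate 2, and their fall was lost without control replicate 1 or 3 and without shKmt2f replicate 1. Kdm5a and Rb1 lost their calls after the GC and length correction (limma adjusted p = 0.134 and 0.171), and 0 p53 targets and 2 inhibitors fell. The recombination list then passed in camera as lower, with adjusted p = 0.00962, and adjusted p = 0.576 with an estimated correlation, where 1 member rose and 1 fell.

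Few markers of cells outside the neural retina were measured at the level needed, namely 4 of 17 vascular, 3 of 9 astrocyte and 3 of 14 pigment epithelium markers. Of the 4 vascular markers 1 fell, Egfl7, from 49.1 ± 6.54 to 25.7 ± 3.41 TPM (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.349). Of 3 astrocyte markers 1 fell, Igfbp2, from 54.0 ± 13.0 to 26.0 ± 4.35 TPM (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.734). Of 3 pigment epithelium markers 1 rose, Dct, from 3.93 ± 0.399 to 6.75 ± 0.943 TPM (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.184). With too few measured members for a list test, the microglial marker C1qa had a log2 fold change of 0.29, the lens marker Bfsp2 had 0.30, and 0 of 8 erythroid genes were measured at the level needed. Of 12 immediate early genes 1 rose, Egr2, and of 8 heat shock genes 2 rose, Hspd1 and Dnaja1, whose levels are uncertain because of pseudogene copies at 503.9 and 77.2 TPM (0 and 5 higher adjusted over each list alone, camera adjusted p = 0.184 and 0.162). Without control replicate 2, 4 immediate early genes, 5 heat shock genes and 2 pigment epithelium markers rose, and without any 1 other library 0 members of these 3 lists rose. The astrocyte fall was lost without shKmt2f replicate 1 or 2, and 1 astrocyte marker rose without control replicate 3. Egfl7, Igfbp2, Dct, Hspd1 and Dnaja1 lost their calls after the GC and length correction, with limma adjusted p between 0.0587 and 0.129, and 1 astrocyte marker rose. The immediate early list then passed in camera as higher, with adjusted p = 0.0232, and adjusted p = 0.576 with an estimated correlation. Of 6 Wnt targets 1 fell, Ccnd1, also adjusted over the list alone (camera adjusted p = 0.0746). In limma 0 of 10 interferon response genes passed, where Ddx58 had 0.75 and Oas2 -0.21, and 0 of 7 Hedgehog genes, where Gli3 had -0.68 and Smo -0.30 (camera adjusted p = 0.803 and 0.376, 0 calls adjusted over each list alone and 1 gene of each at an unadjusted p under 0.05). Of these, 1 interferon response gene rose and 1 Hedgehog gene fell without control replicate 2.

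Chosen after their values were seen, a pair of pseudogenes differed almost completely between the groups. Gm48609, a copy of Rbbp4 on chromosome 13, was listed at 0 in the 3 control libraries and stood at 26.6 ± 1.45 TPM in the shKmt2f libraries, while Rbbp4 and its copies together had a log2 fold change of 0.13 (limma adjusted p = 0.374). Gm8730, a copy of Rplp0 on chromosome 8, stood at 12.9 ± 2.30 TPM in control and 0.102 ± 0.164 TPM in shKmt2f libraries, while Rplp0 and its copies together had -0.10 (limma adjusted p = 0.546).

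The following hypotheses were formed and their lists written after Yars, Rsph1 and Fam183b had been seen among the lowered genes, and the rules for reading the tests were refined after the results. That cytosolic aminoacyl-tRNA synthetases fall as a group was not borne out: with Yars left out, 3 of 22 rose and 0 fell, with camera adjusted p = 0.980. For mitochondrial synthetases, 1 of 16 fell (camera adjusted p = 0.125), and for ciliary genes 4 of 36 fell and 2 rose (camera adjusted p = 0.137), which does not exclude a smaller fall.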
